A study of Mus musculus with 4 samples.

How the data were processed

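The data were 10x 3' single-cell libraries of KPN1 lung tumours in mice, sequenced on a Nextseq 2000 per the labels, with 1 library in each of the groups Control, PD1, Romidepsin and Combination. The deposited matrices hold whole-number UMI counts per gene and cell barcode, with no normalization and 1 library per file. Per the file headers they were written by Cell Ranger 6.1.2, whereas the submitters' notes name Cell Ranger 6.0, Seurat and mm10. The annotation release is not stated. Every barcode held at least 500 UMIs, so barcodes had been filtered before deposit by a filter that is not stated. All libraries list the same 32285 genes.

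Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs, which 3529 Control, 8717 PD1, 7462 Romidepsin and 722 Combination barcodes passed. Doublets were scored with Scrublet in scanpy 1.11.5. Its own threshold called 8, 0, 76 and 6 cells, so the highest scores were removed instead, at 0.8% of the cells per 1000 barcodes and with ties included, which took out 183, 792, 623 and 6 cells. Counts were scaled to the cell total and logged, and 2000 variable genes, 30 principal components and 20 neighbours were used for Leiden clustering at resolution 1 with seed 1, for all libraries together and with no correction between them. Clusters were named from fixed marker lists written before the data were examined. Clusters with fewer than 3 detected markers of every type, with leading genes of another type, with few UMIs and no marker among the leading genes, or with core markers of 2 lineages were left unnamed. T cell and NK clusters shared leading genes at this resolution and were kept as 1 class. At resolution 2 a cluster with the NK genes Klrb1c and Ncr1 among its leading genes stood apart. It held 40 Control, 111 PD1, 30 Romidepsin and 4 Combination cells. CD8 cells were gated within that class by a UMI of Cd8a or Cd8b1 and none of Cd4, and CD4 cells by the converse.

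For each class and library UMIs were summed over cells and scaled to the total of that class and library (CPM). Log2 ratios had 0.5 UMI added to each sum. Their exact 95% intervals come from the conditional binomial distribution of 2 Poisson counts, and those of shares are Clopper-Pearson intervals. All cover counting error only. The intervals of ratios and of CPM treat UMIs as independent, so they leave out variation between cells as well as between libraries. With 1 library per group no test was made and no p-value is given. Where a sum was 0, the ratio is given as a lower bound against a floor of 3 counts, and a share of 0 in the reported B-lineage and CD8 cells with the limit 3 counts allow. Romidepsin was compared as Romidepsin/Control and Combination/PD1, and PD1 as PD1/Control and Combination/Romidepsin, pairs that share no library. Combination was also compared with Control. For 26 gene lists, in classes with at least 30 cells in every library, the members with at least 20 UMIs over a pair were counted as measured, and those past 1.5-fold with an interval outside 1 as higher or lower. The median log2 ratio was set beside 10000 random lists of genes matched in 20 bins of expression. Gated CD8 cells number 21 in Combination, so lists in them were taken for the pairs without that library, a choice made after the data were seen. Of the listed genes, 2 are not in the files. Shares of cells with a UMI of a gene were taken after thinning each cell to 1000 UMIs, with B-lineage cells as the level of free RNA.

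Free RNA carried over from other cells was estimated per class and library as the highest ratio of the CPM of another class's markers in the class to their CPM in all other cells, where the latter was at least 200 CPM. Neutrophil markers were not used for macrophages and monocytes, nor macrophage markers for neutrophils, so the ratio in these classes rests on B and T cell markers. Genes whose highest CPM was under 3 times the predicted carry-over were marked as near it. This step was added after the data were seen.

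Genes were named by a rule written before the data were examined. Eligible genes had at least 20 UMIs in every pair used and at least 50 CPM in 1 library of each. Mitochondrial, ribosomal protein, predicted, haemoglobin, receptor variable and gate genes were not eligible, nor were markers of other cell types. For gated CD8, gated CD4 and macrophage cells, the rule takes the 10 genes per direction for romidepsin, and the 6 for PD1, with the largest smaller log2 ratio of the 2 disjoint pairs, both intervals excluding 1. For Combination/Control it takes 6 per direction not named before. Other classes with at least 100 cells in every library give 5 per direction. Beyond these, 2 to 4 members with the highest and lowest mean ratio are named for each list described, along with Pdcd1, Gzmb, Havcr2, Tcf7, Foxp3 and the class I deacetylase genes. Genes among the 10 with the highest fold in a cluster of the class are said to lead it.

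The alternatives tried were a stricter cell filter (1000 UMIs, 500 genes, 5% mitochondrial), no filter, doublets kept, Leiden resolutions 0.5 and 2, genes centred within each library, CD8 and CD4 cells as T cell subclusters, thinning to 2000 UMIs or none, median-of-ratios scaling, and CPM without mitochondrial, ribosomal and the 50 most abundant genes. Further ones were the mean over cells, 2 UMIs added, list minimums of 1 and 100 UMIs, a 2-fold bound and, after the data were seen, leaving out genes near the predicted carry-over, and taking as T and NK cells the cluster nearest to them that the stricter filter, or no filter, left unnamed. The calculation of the ratio step was checked on sums simulated as Poisson counts, with 200 changed genes per comparison. Intervals of unchanged genes covered 0 in 95.6% (macrophages and monocytes, Combination/Control, 11018 genes) to 97.1% of cases, with 0 calls of the wrong sign. The intervals assume Poisson counts, so this coverage was given by construction. Simulated sums had no variation between cells or libraries, so the shares of differences called hold for counting error only. A simulated difference was called when its interval excluded 1 with the right sign, without the 1.5-fold bound used for lists. In macrophages and monocytes 82.1% of 2-fold differences were called in Romidepsin/Control (13808 genes), and in T and NK cells 88.1% in PD1/Control (11178 genes). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9 were used.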

Results

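Gene expression of single cells was measured in tumours grown from KPN1, a mouse lung tumour line with mutant KRAS and no TP53. There were 4 libraries in 4 groups named Control, PD1, Romidepsin and Combination, with 1 library per group. Romidepsin inhibits class I histone deacetylases, PD1 is the checkpoint inhibition arm, and Combination received both. The sample titles carry a CD45 tag, and CD45 is a surface protein of leukocytes. The labels give no dose, no time and no number of mice per library, and do not say whether tissue was sampled alike. The series text states the aim as the effect of each agent, alone and together, on the tumour microenvironment. With 1 library per group there was no replicate check, so every interval is an exact 95% interval that covers counting error only.

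The Control library held 5244 barcodes with 28784572 unique molecular identifiers (UMIs), and PD1 held 10479 barcodes with 102303472 UMIs. Romidepsin held 9739 barcodes with 96898848 UMIs, and Combination held 892 barcodes with 10188786 UMIs. Median UMIs per barcode were 3458 in Control, 7672 in PD1, 7829 in Romidepsin and 7929.5 in Combination. After filtering, 3346 Control, 7925 PD1, 6839 Romidepsin and 716 Combination cells were kept. The T and NK class held 831, 1234, 972 and 80 cells in that order.

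B-lineage cells were 49.3% of the Control cells (47.6 to 51.0), but 0.719% in PD1 (0.545 to 0.931), 10.2% in Romidepsin (9.50 to 10.9) and 5.45% in Combination (3.90 to 7.37). Macrophages and monocytes, the phagocytes of the tumour, were 14.4% in Control (13.2 to 15.6), 65.6% in PD1 (64.5 to 66.6) and 57.6% in Romidepsin (56.5 to 58.8). They were 32.5% in Combination (29.1 to 36.1), where neutrophils were 45.7% (42.0 to 49.4). Neutrophils were 3.53%, 6.60% and 3.70% in Control, PD1 and Romidepsin. T and NK cells were 24.8% in Control (23.4 to 26.3), 15.6% in PD1 (14.8 to 16.4), 14.2% in Romidepsin (13.4 to 15.1) and 11.2% in Combination (8.96 to 13.7). The B-lineage shares with the stricter filter were 32.3% in Control, 0.469% in PD1, 7.78% in Romidepsin and 1.04% in Combination. With genes centred within each library before clustering, the Combination cells all fell in clusters not named B lineage. The labels leave open whether Control also held lymph node tissue, and every ratio to Control carries that limit. With the stricter cell filter, T and NK cells were 11.4% of Control and 10.99% of PD1 cells, and with no filter 10.6% and 11.9%. Under each of these filters a cluster with Lef1 and Tcf7 among its leading genes was left unnamed by the naming rule and so left the class. It held 243 Control, 211 PD1, 162 Romidepsin and 9 Combination cells with the stricter filter, and 808, 265, 719 and 18 with none. With the stricter filter its first leading genes were the mast cell genes Tpsb2, Cma1, Cpa3 and Mcpt4, but 238, 210, 156 and 9 of its cells were T and NK cells in the reported clustering. Taken as T and NK cells, a choice made after the data were seen, it brought the shares to 26.4% of Control and 14.7% of PD1 with the stricter filter, and to 26.8% and 14.7% with none. Of the list medians and named genes of T cells that a filter turned, none stayed turned with this cluster, although Sell turned to 0.005 in Combination/Romidepsin of gated CD8 cells with the stricter filter.

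**Figure D1:**
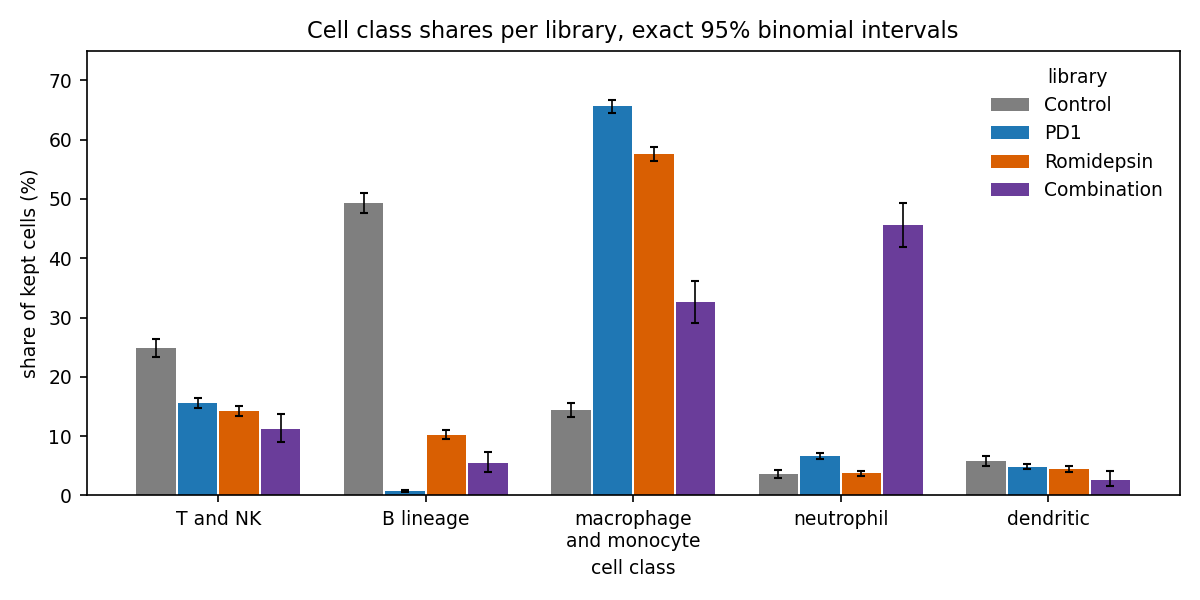
Share of kept cells (%) in 5 cell classes for the 4 libraries, with bars for shares and whiskers for exact 95% binomial intervals. B-lineage cells reach 49.3% in Control, macrophages and monocytes 65.6% in PD1, and neutrophils 45.7% in Combination.

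Several clusters within the macrophage, neutrophil and B-lineage classes held few or no cells of some libraries, while others, such as c12 and c22 of the macrophages and monocytes, were spread over all 4. Cell cycle genes such as Top2a were among the leading genes of c22, and c12 had a median of only 1183 UMIs. At resolution 2 a macrophage cluster of median 1254 UMIs held 5 Control, 10 PD1, 407 Romidepsin and 21 Combination cells. Another, of median 2108 UMIs, held 49, 461, 38 and 5, so c12 need not be a state the libraries share. Cluster c8 held 0 Control, 2 PD1, 1615 Romidepsin and 86 Combination cells, and c15 held 0, 7, 1521 and 88. Cluster c4 held 208 Control, 1195 PD1, 8 Romidepsin and 8 Combination cells, and c13 held 29, 1367, 0 and 1. Of the neutrophils, c16 held 117, 514, 3 and 2 cells and c24 held 1, 9, 250 and 325. Of the B lineage, c0 held 1579, 51, 7 and 2 cells and c1 held 51, 6, 622 and 29. The T and NK class had clusters shared by the libraries. Cluster c2, led by Lef1 and Tcf7, held 440 of 831 Control, 180 of 1234 PD1, 366 of 972 Romidepsin and 4 of 80 Combination cells. Cluster c18, led by Ccl5 and Nkg7, held 94, 590, 216 and 21 of them, and c3, led by Ikzf2, Ctla4 and Foxp3 among others, held 257, 398, 331 and 50. Of the genes named in T cells below, Lef1, Tcf7, Dapl1 and S1pr1 lead c2, Icos, Ctla4 and Foxp3 lead c3, Hist1h1b and Hist1h2ae lead c9, and Gzmb, Ccl5 and Ctsw lead c18, so their ratios in the class move with the mix of clusters.

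The question of effector and exhausted T cells was read first in gated CD8 T cells, of which there were 197, 554, 350 and 21 in Control, PD1, Romidepsin and Combination. Gzmb, the cytotoxic protease granzyme B, was at 284 CPM (UMIs scaled to the total of the class) in Control, 712 in PD1, 246 in Romidepsin and 1210 in Combination. Its 202 UMIs in Combination came from 10 of the 21 cells, and the intervals of ratios leave out such variation between cells. The gene is ENSMUSG00000015437, at 56258838 to 56262260 on chromosome 14 of the mm10 build. Its log2 ratio was 1.32 for PD1/Control (1.17 to 1.49) and 2.30 for Combination/Romidepsin (2.06 to 2.54), which share no library, though the former was 0.33 with the stricter cell filter, or 1.17 with the cluster that this filter left unnamed. For romidepsin it was -0.21 for Romidepsin/Control (-0.41 to -0.01) and 0.77 for Combination/PD1 (0.55 to 0.97). The Combination/PD1 value turned to -0.14 when CD8 cells were taken as T cell subclusters. Pdcd1, which encodes the PD-1 receptor, was at 120, 210, 275 and 246 CPM in Control, PD1, Romidepsin and Combination. Its log2 ratio was 1.19 for Romidepsin/Control (0.94 to 1.46), 0.24 for Combination/PD1 (-0.27 to 0.68) and 0.80 for PD1/Control (0.55 to 1.06). The last turned to -0.26 with the stricter filter, and was 0.48 with the unnamed cluster. Havcr2, which encodes the inhibitory receptor TIM-3, was 0.61 for Romidepsin/Control (0.33 to 0.91) and 0.998 for PD1/Control (0.74 to 1.27), which became -0.22 and -0.07 with the stricter filter, and 0.50 and 0.75 with the unnamed cluster. Tcf7, the transcription factor of naive and progenitor T cells, was -1.16 for Romidepsin/Control (-1.40 to -0.92) and -1.97 for PD1/Control (-2.21 to -1.73), but 1.18 for Combination/PD1 (0.52 to 1.73). With CD8 cells taken as subclusters, Tcf7 was 0.91 for Romidepsin/Control. That setting took a subcluster of 424 Control and 19 Romidepsin cells with Tcf7 at 560 CPM as neither CD8 nor CD4, and one of 5 Control and 351 Romidepsin cells with Tcf7 at 452 CPM as CD8.

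**Figure D2:**
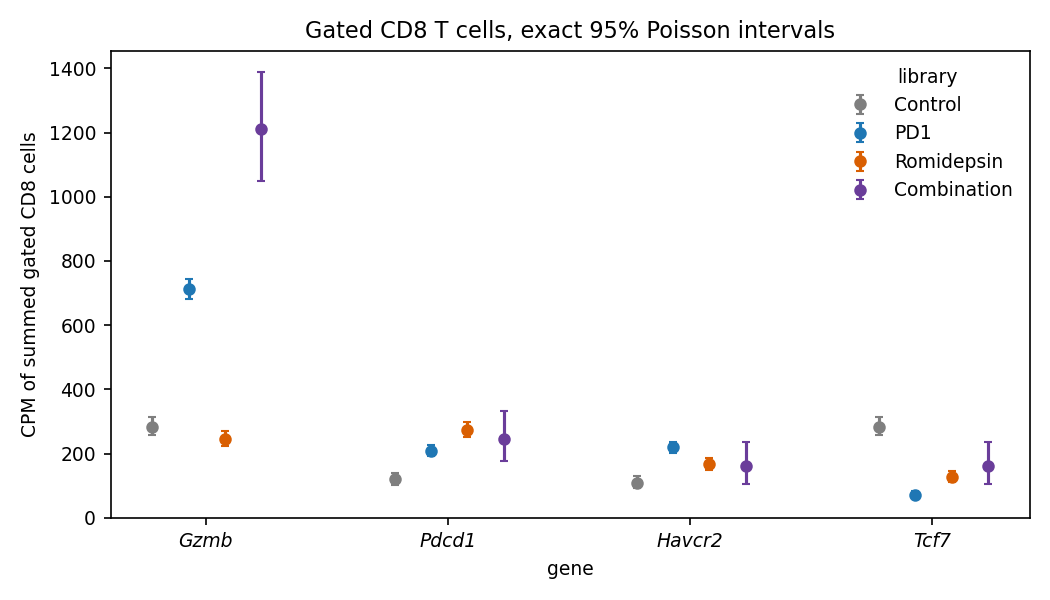
CPM of Gzmb, Pdcd1, Havcr2 and Tcf7 in the summed gated CD8 T cells of each library, with points for values and whiskers for exact 95% Poisson intervals. Gzmb is at 712 CPM in PD1 and 1210 in Combination, above 284 in Control and 246 in Romidepsin.

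Thinned to 1000 UMIs per cell, 16.9% of the T and NK cells of Control were gated CD8 (14.5 to 19.7), against 33.2% in PD1 (30.6 to 36.0), 24.2% in Romidepsin (21.5 to 27.2) and 17.5% in Combination (9.91 to 27.6). Unthinned, the shares were 23.7%, 44.9%, 36.0% and 26.3%. Gated CD4 cells were 16.2%, 10.4%, 9.80% and 22.5% thinned, and 42.2%, 22.9% and 21.2% unthinned in Control, PD1 and Romidepsin, with 40 of 80 cells in Combination. Foxp3, the factor that defines regulatory T cells, had a UMI in 7.46% (3.64 to 13.3), 16.9% (10.8 to 24.7), 14.6% (8.01 to 23.7) and 11.1% (1.38 to 34.7) of thinned gated CD4 cells, the last being 2 of 18 cells. Unthinned, it had one in 24.8%, 30.5% and 41.7% in Control, PD1 and Romidepsin and in 16 of 40 cells in Combination, another order of the libraries. Thinning left out 5, 39, 64 and 0 T and NK cells with too few UMIs.

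Gzmb had a UMI in 12.7% of thinned gated CD8 cells in Control (8.38 to 18.2), 27.3% in PD1 (23.6 to 31.2), 10.9% in Romidepsin (7.80 to 14.7) and 28.6% in Combination (11.3 to 52.2). Pdcd1 had one in 6.60% (3.56 to 11.02), 18.0% (14.9 to 21.5), 17.7% (13.8 to 22.2) and 28.6% (11.3 to 52.2), in the same order. Both genes had one in 2.54%, 5.82%, 3.24% and 9.52% of these cells. Havcr2 had one in 7.11%, 18.0%, 13.3% and 0% of them, though 38.1% of the 21 Combination cells held a UMI of it before thinning. Gzmb and Havcr2 together had UMIs in 4.06%, 7.82%, 3.54% and 0%. For cells with a UMI left after thinning, 0 of 21 allows up to 14.3%, which is no limit on expression. Tcf7 had one in 21.8%, 6.36%, 15.3% and 14.3%. Unthinned, Gzmb shares were 21.3%, 48.2%, 27.4% and 47.6%, Pdcd1 shares 18.8%, 49.3%, 43.1% and 61.9%, Havcr2 shares 18.8%, 47.1%, 34.9% and 38.1%, and Tcf7 shares 58.9%, 16.1%, 29.7% and 28.6%. Thinned B-lineage cells, which should lack the genes, had Gzmb in 0.31%, Pdcd1 in 0.062%, Havcr2 in 0.062% and Tcf7 in 0.31% in Control, and 0%, 0.145%, 0% and 0.726% in Romidepsin, where 0 of 689 cells allows up to 0.435%. No B-lineage cell of PD1 (0 of 54, allowing up to 5.56%) or Combination (0 of 37, up to 8.11%) had any of the 4 genes. Median depth before thinning was 5540, 4337, 3937 and 6813 UMIs in these CD8 cells and 4224, 3444, 6571 and 13496 in the B-lineage cells, and 0, 4, 11 and 0 CD8 cells were left out. With the stricter filter, Gzmb was in 37.3% of 51 Control and 34.6% of 381 PD1 gated CD8 cells. With the cluster led by Lef1 and Tcf7 that this filter left unnamed, it was in 11.7% of 111 Control and 31.45% of 407 PD1 cells. Tcf7 was in 7.84%, 3.41%, 0.61% and 0% of gated CD8 cells with the stricter filter, and in 8.78% in Romidepsin with that cluster.

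The genes named in gated CD8 cells for romidepsin against no romidepsin were chosen for differing the same way in both disjoint pairs. Serpine2, a secreted protease inhibitor, had a log2 ratio of 2.47 for Romidepsin/Control (1.98 to 3.03) and 2.17 for Combination/PD1 (1.76 to 2.55). The gene is ENSMUSG00000026249, at 79794197 to 79861180 on chromosome 1. The metallothioneins Mt1 and Mt2, which bind zinc and copper, were at 4.03 (3.62 to 4.51) and 4.75 (3.84 to 6.06) for Romidepsin/Control, and both at 1.98 for Combination/PD1. Nmrk1, a kinase of NAD synthesis, was at 2.42 (1.81 to 3.14) and 2.10 (1.37 to 2.72). Hilpda, which coats lipid droplets, was at 1.63 and 2.18, and Hk2, the first enzyme of glycolysis, at 1.19 and 1.22. Sytl3, Arl14ep, Snhg9 and Gabarapl1 were higher too, at 1.38 to 1.84 in Romidepsin/Control. The chemokine Ccl3 was lower, at -1.89 (-2.13 to -1.66) and -1.45 (-2.20 to -0.84). Rnf213, a large ubiquitin ligase, was at -1.50 (-1.97 to -1.04) and -1.47 (-3.53 to -0.26), the former turning to 0.03 with CD8 cells taken as subclusters. Cd7, Sntb2, Rasgrp2, Kmt5b, Sp110, Commd8, Trmt1l and Ankrd44 were lower in both pairs, with 1 to 29 UMIs each in Combination. In all, 108 of 2738 eligible genes were higher and 172 lower in both pairs. Genes that differed in opposite ways were not counted, and over 8501 genes the 2 pairs had a Pearson r of 0.007. The counts therefore do not show that the pairs agree.

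In gated CD4 cells, romidepsin libraries were higher in the small nucleolar host genes Snhg9 (2.28 and 2.04), Snhg3 (1.82 and 1.57) and Zfas1 (1.29 and 1.31). Sv2c was at 3.64 and 1.38, Nmrk1 at 2.83 and 1.47, Sytl3 at 2.40 and 1.46, Hist1h4i at 1.65 and 2.27, and Unc119 at 1.35 and 1.58. Mt2 was at 5.21 and 1.85, near the level predicted for free RNA, and Nrgn at 3.12 and 1.54. Lef1 was lower, at -1.77 (-2.09 to -1.48) and -1.28 (-2.08 to -0.64), and Bach2, a repressor of effector programmes, at -1.77 and -1.67. Igfbp4 was at -4.36 (-5.44 to -3.57) in Romidepsin/Control and, with 0 UMIs in Combination, at least 5.41-fold lower than in PD1. Rasgrp1, which couples the T cell receptor to Ras, was at -1.84 and -1.83, and the chaperone Hsph1 at -1.35 and -1.53. Actn1, Ddx58, Trim12a, Ppm1h and Rassf2 were lower in both pairs. Foxp3 was at 0.64 for Romidepsin/Control (0.39 to 0.89) and -0.04 for Combination/PD1 (-0.49 to 0.38). With CD4 cells taken as subclusters, Foxp3 (-0.40), Igfbp4 (0.34) and Actn1 (0.74) turned direction in Romidepsin/Control, Nrgn had 0 UMIs in both libraries, and with the stricter filter Actn1 (0.33), Trim12a (0.15) and Ppm1h (0.21) did. With the cluster that this filter left unnamed, the last 3 were at -2.42, -1.08 and -0.66. In Combination/PD1, Actn1 turned to 0.12 with subclusters and Nrgn to -0.78 with the stricter filter (0.68 with the unnamed cluster).

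A list member counts here as higher or lower when its ratio passed 1.5-fold with an interval that excluded 1. Of the naive and progenitor list in T and NK cells, 14 of 20 members were lower and 1 higher in Romidepsin/Control, with a median log2 ratio of -0.96, below which lay 0 of 10000 expression-matched random lists. The count of lower members was 6 with the stricter filter, 14 with the unnamed cluster and 8 with the 2-fold bound. In Combination/PD1, 8 of 19 were lower and 3 higher, with a median of -0.50 and 85 random lists below it, which turned to 0.18 with no cell filter and was -0.29 with the unnamed cluster. Dapl1 was at -2.01 and -1.91, while Il7r, the receptor for interleukin 7, was at 0.82 and, short of the 1.5-fold bound, at 0.47. The T cell receptor complex list had 6 of 22 members lower and 2 higher (-0.41, 0 random lists below), and 7 lower and 2 higher in Combination/PD1 (-0.36, 262 below). Prkcq, a kinase of receptor signalling, was at -1.04 (-1.22 to -0.86) and -1.12 (-1.64 to -0.67), and Icos was higher at 0.67 and 0.81. The regulatory T cell list had 7 of 21 members higher (0.33, 9992 below) and 9 of 20 (0.42, 9996 below), with Ctla4 at 0.99 (0.89 to 1.09) and 1.85 (1.71 to 1.98), though the first median was -0.20 with the stricter filter and 0.18 with the unnamed cluster. Cluster c3, with Ctla4 and Foxp3 among its leading genes, was 34.1% of the T and NK cells of Romidepsin against 30.9% of Control, and 62.5% of Combination against 32.3% of PD1, so the mix of clusters differed as well. The interferon response list had 18 of 32 members lower in Romidepsin/Control (-0.69, 0 below) and 2 of 33 in Combination/PD1 (-0.10, or -0.09 with members at 0 at their bound, 5477 below). Sums of this class were also simulated with counting error only. Intervals of 1.5-fold differences then excluded 1, with the right sign, in 65.67% of cases in Romidepsin/Control and 41.79% in Combination/PD1. The 1.5-fold bound was not applied there, so these are not call rates for list members. Glycolysis and hypoxia genes had 13 of 22 members higher (0.75, 10000 below), against 4 of 22 in Combination/PD1 (-0.01, 7044 below).

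The cytotoxic effector list went opposite ways in the romidepsin pairs. In T and NK cells, 12 of 24 members were higher and 1 lower in Romidepsin/Control (0.59, 10000 random lists below), but 0 of 23 higher and 12 lower in Combination/PD1 (-0.69, 0 below). The 12 higher became 7 with the stricter filter, and 10 with the unnamed cluster. Cx3cr1 was at 2.29 and 0.18, Ctsw at -0.59 and -3.56, and Gzmc at 1.46 and -3.81. At resolution 2, Ctsw and Gzmc were among the leading genes of a cluster with the NK genes Klrb1c and Ncr1. That cluster held 40 Control, 111 PD1, 30 Romidepsin and 4 Combination cells, while the T and NK class held 831, 1234, 972 and 80. Its share was thus lower in Romidepsin than in Control, although Gzmc was higher there. The share was also lower in Combination than in PD1, as were both genes. How much of those ratios the share of NK cells explains was not tested. The exhaustion and inhibitory receptor list had 11 of 25 members higher and 0 lower (0.58, 10000 below), then 5 higher and 8 lower (-0.18, 3244 below). Its member Tigit was at 0.82 and 2.14 and Cd160 at -0.50 and -1.90. The Romidepsin/Control median of that list was -0.02 with the stricter cell filter, when 2 members were higher, and 0.45 with the unnamed cluster, when 10 were. In gated CD8 cells the cytotoxic list stood at 0.48 and the exhaustion list at 0.36 for Romidepsin/Control, which became -0.08 and -0.34 with that filter, 0.45 and 0.18 with the unnamed cluster, and -0.13 and -0.51 with subclusters. In gated CD8 cells, 14 of 29 interferon members were lower (-0.77, 0 below) and 12 of 20 glycolysis members higher (0.71, 10000 below). In gated CD4 cells, 16 of 20 naive members were lower in Romidepsin/Control (-1.07, 0 below) and 9 of 18 in Combination/PD1 (-1.19, or -1.13 at the bound, 0 below). The former turned to 0.08 with the stricter filter, and was -0.91 with the unnamed cluster.

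**Figure D3:**
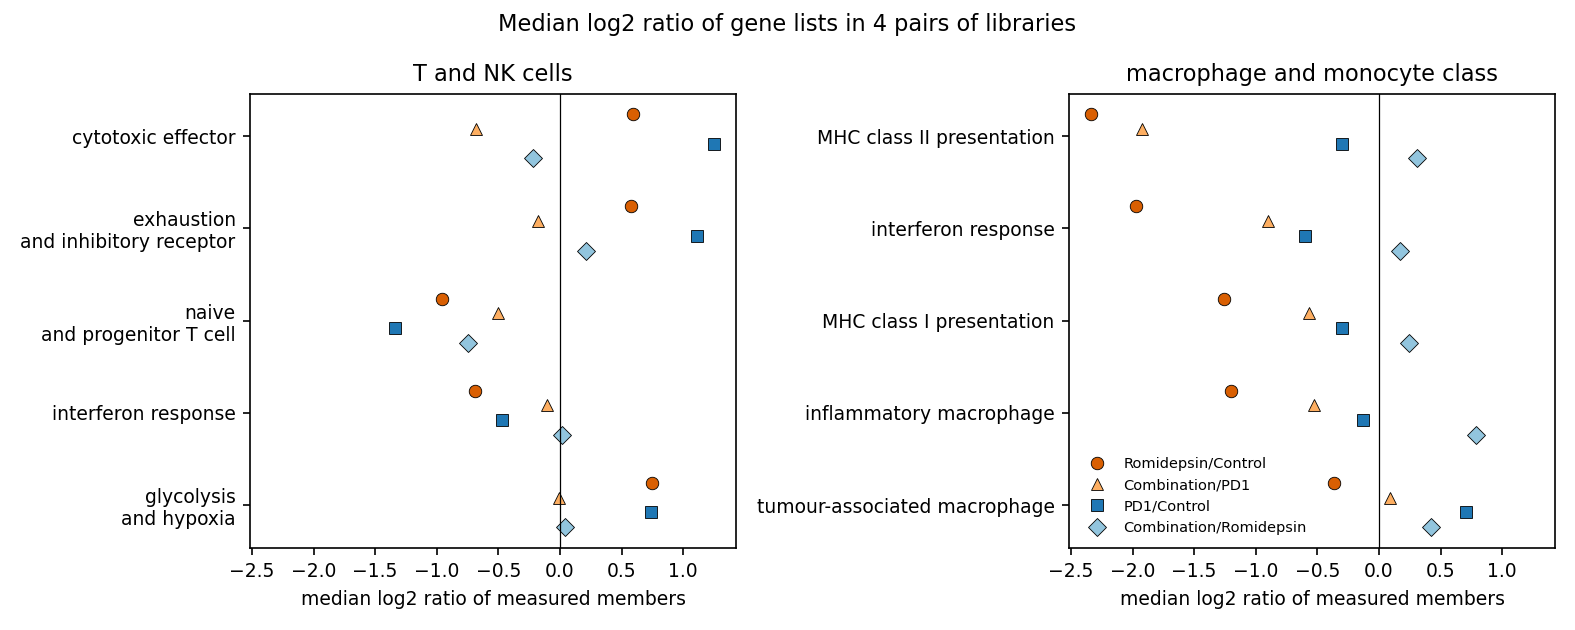
Median log2 ratio of the measured members of 5 gene lists in T and NK cells and 5 in macrophages and monocytes, with 1 symbol per pair of libraries. The cytotoxic list lies at 0.59 and -0.69 in the 2 romidepsin pairs, and the class II list in macrophages at -2.33 and -1.92.

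In macrophages and monocytes, the genes of MHC class II presentation were lower in both romidepsin pairs. Of 12 list members, 11 were lower and 0 higher in Romidepsin/Control, with a median of -2.33, and 10 were lower and 0 higher in Combination/PD1, with a median of -1.92. No random list of 10000 lay below either median. Ciita, the master activator of class II genes, was at -5.05 (-5.24 to -4.87) and -4.25 (-4.86 to -3.75), or 193, 134, 5.80 and 6.90 CPM in Control, PD1, Romidepsin and Combination. The gene is ENSMUSG00000022504, at 10480059 to 10528418 on chromosome 16. H2-Ab1, a class II chain, was at -3.57 (-3.60 to -3.54) and -2.67 (-2.73 to -2.61). Of the interferon response list, 33 of 35 members were lower and 0 higher (-1.97, 0 random lists below), and in Combination/PD1 23 were lower and 2 higher (-0.90, or -0.89 at the bound, 0 below). Cxcl9, an interferon-induced chemokine that also leads a cluster, was at -4.04 and -4.13. Class I presentation genes had 19 of 21 members lower (-1.26, 0 below) and 10 of 21 (-0.56, 118 below), with the proteasome subunit Psmb10 at -1.93 and -1.53. The inflammatory macrophage list had 15 of 22 members lower and 2 higher (-1.20, 0 below), then 10 lower and 4 higher (-0.53, or -0.36 at the bound, 286 below). Its costimulatory member Cd40 was at -3.63 and -2.39, whereas Il6 was at 2.19 and 2.64.

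Of the 10 genes named as higher with romidepsin in this class, 5 (Wfdc21, Ppbp, Mmp8, Prtn3 and Chil3) also lead clusters c8, c15 or others of the class. The other 5 were Lcn2, an iron-siderophore binding protein (7.07 and 6.68), Mt2 (5.63 and 4.19), the protease inhibitors Slpi (3.37 and 3.79) and Serpine1 (3.82 and 3.35), and Selenom (3.07 and 2.92). Lcn2 is also among the leading genes of the neutrophil cluster c24, found mostly in the romidepsin libraries. Free RNA in macrophages was not estimated from neutrophil markers. Of the 10 lower genes, Retnla, Ccl8, Fcrls, Cxcl9, Vcam1 and Cfb lead clusters as well. The remaining lower genes were Ciita, Slamf8 (-3.89 and -3.46), Tmem176a (-3.14 and -3.10) and Tmem176b (-3.02 and -2.96). Genes known to respond to deacetylase inhibitors had 8 of 15 members higher (1.10, 10000 random lists below) and 6 of 14 (0.40, 9859 below), with the linker histone Hist1h1c at 2.65 (2.45 to 2.86) and 1.66 (1.54 to 1.78). Glycolysis and hypoxia genes had 8 of 22 (0.42, 9993 below) and 13 of 22 members higher (0.67, 10000 below), with Ero1l, which leads c11, at 1.47 and 1.85. Of romidepsin's targets, Hdac1 was at 0.33 (0.19 to 0.47) and 0.21 (0.04 to 0.37), Hdac3 at 0.39 and 0.43, Hdac2 at -0.50 (-0.73 to -0.26) and -0.62, and Hdac8 at -0.21 and -0.24. The class I HDAC list had 3 of 18 members lower (-0.26, 2205 below) and 6 of 18 (-0.28, 3823 below). In T and NK cells 0 of its 18 members passed the bound in Romidepsin/Control, and Hdac1 was at -0.04 and 0.11. The median-of-ratios scaling would add 0.12 to each log2 value of Romidepsin/Control and 0.20 to each of Combination/PD1 in macrophages, a shift smaller than the class II and interferon medians.

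Neutrophils also differed in both romidepsin pairs, which compare mostly cluster c24 of the romidepsin libraries with c16 of the others. Clec4n, the receptor dectin-2, was at -7.45 (-8.88 to -6.49) and -8.30 (-9.71 to -7.35), and Prr5l and Scimp were lower by comparable amounts. Oasl2, an interferon-induced gene that also leads c16, was at -7.51 and -5.98. Ifit3, with 0 UMIs in Romidepsin, was at least 35.7-fold lower than in Control and at -5.92 in Combination/PD1. Elane, neutrophil elastase, had 0 UMIs in Control and PD1, and was at least 8.49-fold and 20.5-fold higher in Romidepsin and Combination. Prtn3 was at 4.29 (2.74 to 7.66) and 4.62 (3.66 to 6.04), Prnp at 5.57 and 4.13, and Bex3 and Hist3h2ba were higher too. The interferon list had 18 of 23 members lower (-3.55, 0 random lists below) and 26 of 32 (-3.37, 0 below), and none was higher. Immediate early genes had 23 of 25 lower (-2.56, 0 below) and 19 of 25 (-1.05, 113 below), with Nr4a3 at -4.98 and -4.19. The inflammatory list had 12 of 15 (-2.55, 2 below) and 13 of 18 lower (-2.50, 0 below), with Il1a at -6.84 and -4.19. Class I presentation had 12 of 16 (-1.29, 209 below) and 16 of 21 members lower (-0.96, 243 below). Oxidative phosphorylation genes had 18 of 21 (1.24, 10000 below) and 16 of 21 members higher (1.06, 9998 below), with Uqcrq at 2.04 and 1.64. Scaling matters here, since median-of-ratios would add 0.75 to each log2 value of Romidepsin/Control and 0.62 to each of Combination/PD1.

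For PD1 against no PD1, T and NK cells of the PD1 library were higher than Control in cytotoxic and exhaustion genes and lower in naive genes. Of the cytotoxic list, 21 of 23 members were higher and 0 lower (1.25, 10000 random lists below), but in Combination/Romidepsin 2 of 24 were higher and 8 lower (-0.22, 14 below). Gzmb was at 1.92 (1.79 to 2.05) and 1.87 (1.69 to 2.05) and Gzmk at 1.98 and 0.08, while Ctsw was at 1.13 and -1.83. The exhaustion list had 17 of 25 members higher (1.11, 10000 below) and 5 of 25 (0.21, 9751 below), with Entpd1, an ATP-degrading enzyme, at 1.83 and 0.40. The naive list had 15 of 20 members lower (-1.34, 0 below) and 9 of 19 (-0.75, 0 below), with Dapl1 at -3.15 (-3.51 to -2.81) and -3.04 (-6.42 to -1.48) and S1pr1, the egress receptor, at -1.63 and -1.18. Chemokines and their receptors had 11 of 17 members higher and 2 lower (1.08, 10000 below), and 4 of 15 higher and 4 lower (0.22, 9408 below), with Ccl1 at 3.08 and 1.34. Immediate early genes had 8 of 27 (0.36, 9981 below) and 11 of 27 members higher (0.57, 10000 below), with Nr4a3 at 0.87 and 1.22. Glycolysis genes had 14 of 22 higher in PD1/Control (0.74, 10000 below) and 1 of 22 in Combination/Romidepsin (0.04, 5374 below), and interferon genes 13 of 34 lower (-0.47, 0 below) and 0 of 29 (0.02, 4525 below). With the stricter cell filter, 13 cytotoxic and 11 exhaustion members were higher in PD1/Control and the immediate early median was -0.08, against 18, 17 and 0.35 with the cluster that this filter left unnamed. The median-of-ratios scaling would add -0.13 to each PD1/Control value of this class. In gated CD8 cells the cytotoxic median (0.89) became -0.08 and the exhaustion median (0.88) -0.02 with that filter, and 0.69 and 0.63 with the unnamed cluster.

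In gated CD8 cells 132 of 2695 eligible genes were higher and 26 lower in both PD1 pairs. Here too genes that differed in opposite ways were not counted. Over 7846 genes the pairs had a Pearson r of -0.1, so the counts do not show that they agree. The genes named as higher were Gzmb, Serpine2 (1.74 and 1.45), the NK receptor Klrc2 at 1.34 (0.99 to 1.72) and 1.91 (1.40 to 2.37), Entpd1 (1.44 and 1.19), Tff1 (1.91 and 1.11) and Fam129a (1.21 and 1.08). Those named as lower were Dapl1 (-3.65 and -2.68), the lymph-node homing receptor Sell at -2.31 (-2.57 to -2.06) and -1.23 (-2.45 to -0.35), Cmah (-1.80 and -1.35), Dennd2d (-1.25 and -1.43), Il6st (-1.19 and -1.76) and Pdk1 (-0.95 and -1.41). Il6st turned to 0.05 in PD1/Control with the stricter filter, and Cmah (0.62) and Dennd2d (0.27) in Combination/Romidepsin with no filter. Dennd2d also turned to 0.10 in PD1/Control with subclusters. With the clusters that these filters left unnamed the values were -1.06, -1.16 and -0.56, and Sell was 0.005 in Combination/Romidepsin with the stricter filter. The 17 of 19 naive members lower in PD1/Control gave a median of -1.75. Gated CD4 cells had Ccl1 at 7.28 (6.08 to 9.33) and 2.48 (1.73 to 3.27), Ccl5 at 2.94 and 1.74, Gzmb at 1.83 and 2.74, Rgs16 at 2.15 and 2.22, Tnfsf11, the cytokine RANKL, at 1.93 and 1.94, and Camk2n1 at 2.30 and 1.25. Birc5 was lower, at -0.92 and -1.09, Ube2c at -1.06 and -1.41, Hist1h1b at -0.93 and -0.98, and Hist1h2ae at -1.34 and -0.89. Sell was at -0.79 and -1.78 and S1pr1 at -1.06 and -0.95. In Combination/Romidepsin, Birc5 (2.67), Ube2c (0.38), Hist1h1b (1.62) and Hist1h2ae (0.88) turned with subclusters. With the stricter filter Ccl1 and Tnfsf11 had 0 UMIs in Combination, and with the unnamed cluster they were at 2.52 and 1.36. Among CD4 cells the naive list had 12 of 20 members lower in PD1/Control (-0.93) and 6 of 16 in Combination/Romidepsin (-0.54), with 0 random lists below either.

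In macrophages and monocytes, the genes named as higher in both PD1 pairs included Ccl7, a monocyte attractant, at 1.59 (1.44 to 1.75) and 2.01 (1.92 to 2.10), Cxcl1 at 1.09 and 1.39, Pdpn at 2.09 and 1.47, and Pltp at 1.09 and 1.13. Ms4a7 (1.18 and 1.68) and Pf4 (1.12 and 1.08) also lead clusters of the class. The monocyte gene Ly6c2 was lower, at -1.53 (-1.61 to -1.45) and -0.78 (-0.86 to -0.70), as were Hes1 (-1.16 and -0.64), Gsr (-1.20 and -0.61), Hp (-0.97 and -0.63), Sorl1 (-0.68 and -0.90) and Sp100 (-0.66 and -0.63). The tumour-associated macrophage list had 15 of 29 members higher and 2 lower (0.70, 10000 random lists below), and 10 higher and 1 lower (0.42, 10000 below). The scavenger receptor Cd163 was at 1.69 and 3.32 and the folate receptor Folr2 at 2.52 and 1.71. Both lead c13, which was 6.03% of the class in Control and 26.3% in PD1, so the list moves with that cluster in PD1/Control. Myeloid chemokines had 9 of 21 members higher in each pair (0.37, 9999 below, and 0.45, 10000 below). Lysosome and phagocytosis genes had 10 of 24 (0.40, 10000 below) and 3 of 24 members higher (0.01, or 0.02 at the bound, 7323 below). In neutrophils, Cxcl10 was at 1.47 and 1.76, Camp, a granule peptide gene that also leads a cluster, at 3.27 and 1.09, Slbp at 1.21 and 1.25 and Atf2 at 1.28 and 0.94. Hes1 (-0.95 and -1.89), Iqgap2, Pnpla2, Zfp638 and Zcchc7 were lower in both pairs.

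For Combination against Control, gated CD8 cells were higher in Ermn at 5.89 (4.11 to 9.33), Myo10 at 3.29, the mitophagy gene Bnip3 at 3.004 (1.66 to 4.35), Plscr1 at 2.67, the cytokine Il10 at 2.55 (1.38 to 3.65) and Arid3a at 2.48. With 0 UMIs in the 21 Combination cells, the chemokine Xcl1 was at least 7.19-fold lower, the deacetylase gene Hdac7 at least 6.98-fold, Hist1h1b 4.196-fold, Igfbp4 3.74-fold, Gal 3.53-fold and Id3 2.83-fold. Gal had 85 UMIs in Control and 1 in all other libraries, and with the stricter filter or subclusters it had 0 UMIs in both Combination and Control, so no ratio. Among gated CD4 cells Lgals7 was at 4.99 (3.87 to 6.49), with 0 UMIs in Combination under subclusters, Tg at 4.45, Chpt1 at 3.32 and Ier5l at 3.01, and Mt1 and Ier3 were near the level predicted for free RNA. Dapl1 was at least 9.70-fold lower, and Dtx1, a target of Notch, was at -3.27 (-6.64 to -1.71). In macrophages the acute phase gene Saa3 was at 7.43 (6.70 to 8.39), Il6 at 3.47 (2.92 to 4.11) and the scavenger receptor Cd36 at 3.38 (3.08 to 3.72), and Nos2, Ecm1 and Ccl2 lead clusters. Spon1 was at -5.75, Adgre4 at -5.37, Serpina3g at -5.30, Ace at -4.91 and Ly6i at -4.64. In neutrophils Cstdc5, Polr2l and Stom had 0 UMIs in Control and were at least 25.8-fold, 14.9-fold and 7.23-fold higher, and the chemokine Ccl4 was at -6.86 (-7.31 to -6.46). In T and NK cells 14 of 20 naive members were lower (-1.69, 0 random lists below), and 14 of 25 exhaustion (0.75, 10000 below) and 13 of 21 regulatory members (0.72, 10000 below) were higher. The 9 of 23 cytotoxic members higher (0.37, 9949 below) became 2 with the stricter filter, at a median of -0.22, and 8 with the unnamed cluster, at 0.18. The 14 exhaustion members higher became 3 with the stricter filter and 6 with no filter, or 12 and 15 with the unnamed clusters, and the 14 naive members lower became 9 with the stricter filter, or 16.

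The departure from additivity is log2 of Combination times Control over PD1 times Romidepsin, in CPM. In gated CD8 cells it was 0.98 for Gzmb, -0.95 for Pdcd1, -1.03 for Havcr2 and 2.33 for Tcf7, against a median of -0.15 over 8501 genes (quartiles -0.80 and 0.40). In macrophages and monocytes the median was -0.10 over 13132 genes.

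Across genes, which are not independent replicates, the log2 ratios of Romidepsin/Control and Combination/PD1 had a Pearson r of 0.770 in neutrophils (rho 0.774), 0.621 in macrophages and monocytes (rho 0.576) and 0.513 in the B lineage (rho 0.603). In gated CD4 cells r was 0.164 (rho 0.242), in T and NK cells 0.070 (rho 0.187), and in gated CD8 cells 0.007 (rho 0.071). PD1/Control and Combination/Romidepsin had r from -0.189 in neutrophils to -0.061 in macrophages and monocytes. With genes centred within each library before clustering, the macrophage values were 0.405 and -0.341. With the stricter filter the B-lineage value for romidepsin was 0.348. Without genes near the predicted level of free RNA, a choice made after the data were seen, the romidepsin value was 0.30 in gated CD4 and 0.239 in T and NK cells, and the PD1 values of -0.064 and -0.178 became 0.080 and -0.019. That level was set by markers of other classes. For each library it was the highest ratio, over the marker sets used, of their CPM in the class to that in other cells. In gated CD4 cells this ratio was 4.88%, 20.73%, 14.14% and 15.91% in Control, PD1, Romidepsin and Combination. In T and NK cells it was 3.69%, 10.49%, 10.3% and 11.4%. Neutrophil markers gave it in Control and PD1, and B-lineage markers in Romidepsin and Combination. In gated CD4 cells of Combination, macrophage and neutrophil markers gave only 0.55% and 0.4%. In those of Romidepsin they gave 5.82% and 3.56%. The highest ratio thus need not hold for free RNA of every source. The tumour-associated macrophage list stood in T and NK cells at 1.51 for Romidepsin/Control and 2.58 for PD1/Control, and at 0.37 and 0.31 without genes near the predicted level.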

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

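Of the tests in this part, that of other scalings of the class II genes was chosen only after the result was seen, and those on free RNA, on cells with Ly6c2 and on CD8 cells without naive genes use steps added after the data, though not these results, were seen.

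Several values went opposite ways in pairs of libraries that answer the same question, and these differences were not tested. The B-lineage share was 4.73 points higher in Combination than in PD1, against -39.1 points in Romidepsin/Control. The Combination and PD1 shares were 1.04% and 0.469% with the stricter filter, and 0% and 0.707% with genes centred within each library, where the first difference thus turned. The same cells were kept under centring, so the 39 B-lineage cells of Combination fell in clusters not named B lineage. The 0% therefore does not show an absence of such cells. The macrophage and monocyte share was at -33.1 points in Combination/PD1 against 43.3 in Romidepsin/Control, and at -25.1 in Combination/Romidepsin against 51.2 in PD1/Control. All shares of a library are parts of the same total, and neutrophils were 45.7% of Combination cells, against 6.60% in PD1 and 3.70% in Romidepsin. A larger neutrophil share lowers the macrophage share by construction, so the negative values do not show fewer macrophages. The cytotoxic median in T and NK cells was -0.69 in Combination/PD1 against 0.59 in Romidepsin/Control, and -0.22 in Combination/Romidepsin against 1.25 in PD1/Control. In macrophages and monocytes the PD1 contrast had class II genes at 0.31 in Combination/Romidepsin against -0.30 in PD1/Control, interferon genes at 0.17 against -0.60, and inflammatory genes at 0.79 against -0.13.

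Clusters left unnamed, which no comparison uses, held more cells in some libraries than in Control. Cluster c17, of low UMI counts and led by Lgals2, Wfdc2 and the epithelial genes Krt18, Krt19 and Krt8, was 1.93% of PD1 and 1.48% of Romidepsin cells, against 0.687% of Control. Cluster c20, led by Ctsk, Acp5 and Mmp9, was 3.24% of PD1, 0.453% of Romidepsin and 1.82% of Combination cells, against 0.03% of Control.

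Class II presentation genes were lower in macrophages and monocytes of both romidepsin libraries. In cells of the class with a UMI of the monocyte gene Ly6c2, the median was -2.53 in Romidepsin/Control (2699 and 175 cells, 10 of 12 members lower) and -1.82 in Combination/PD1 (144 and 1002 cells, 10 of 12 lower), which argues against a different share of Ly6c2-positive cells as the whole cause. The gate cannot test a different mix of cell states. Clusters c8 and c15 were 41.0% and 38.6% of the class in Romidepsin and held 0 Control cells. Predicted free RNA made up 3.01% of the summed class II CPM of 29463 in Control and 0.818% of 25910 in PD1, which argues against free RNA. Under 2 other scalings the highest of 4 medians was -1.72, which argues against scaling. A lower expression of class II genes with romidepsin may explain the pattern, as may a different mix of cell states. Each group is 1 library, so other differences between the libraries stay open as well.

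Naive genes were lower and cytotoxic genes higher in T and NK cells of PD1 than of Control. Without genes near the predicted free RNA the cytotoxic median was 1.24 over 22 members, which argues against free RNA from cells outside the class. Free RNA released by T and NK cells themselves was not estimated, so this value cannot test it. In gated CD8 cells with no UMI of Sell, Ccr7, Lef1 or Tcf7 (41 Control and 367 PD1 cells) the cytotoxic median was 0.11 over 21 members, of which 3 were higher and 5 lower. Those cells were split by genes of the pattern itself, so the value decides nothing. A different mix of resting and activated T cells and a change within cells cannot be told apart. PD1 treatment, or lymph node tissue in Control if tissue was not sampled alike, also stays open and was not tested.

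In neutrophils of the romidepsin libraries Bex3, Elane, Hist3h2ba, Prtn3 and Prnp were higher and Clec4n, Scimp, Prr5l, Oasl2 and Ifit3 lower. With no cell filter the median of the 5 lower genes was -7.47 in Romidepsin/Control (-6.84 with genes at 0 at their bound, 260 and 113 cells) and -6.90 in Combination/PD1 (336 and 524 cells), which argues against removal of mature neutrophils by the filter used here. With that filter the class held 253 and 118, and 327 and 523 cells, so it changed little. Barcodes had been filtered before deposit, and a loss of neutrophils at that step cannot be tested. Predicted free RNA gave a median of 1.17% of the CPM of the 5 higher genes in Romidepsin (highest 7.93%) and 0.339% in Combination (highest 1.20%), which argues against free RNA at the level set by B and T cell markers. Macrophage markers were not used for that level. Cluster c16 held 99.2% of the neutrophils of Control and 98.3% of those of PD1, and c24 held 98.8% in Romidepsin and 99.4% in Combination. The ratios thus compare nearly separate clusters. A change of state within cells and a different mix of neutrophils cannot be told apart. Either may go with romidepsin, and a difference between single libraries stays open.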

How the results depend on the processing

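The alternative without genes near the predicted level of free RNA, those that take an unnamed cluster as T and NK cells, and the lists in gated CD8 cells were chosen after the data were seen. A change of sign was counted as a turn only where the reported value stood out. Medians had to be at least 0.25 in size and in a tail of the random lists, and gene intervals had to exclude 1. Other changes of sign are counted as close or moved. Of 2608 values of list medians under 16 alternatives, 2327 stayed close to the reported value, 253 moved further and 28 turned. By this count 166 of 185 medians never turned. Of 3707 values of named genes, 3215 stayed close, 456 moved and 36 turned, and 289 of 317 gene results never turned by this count. Of 352 values of the shares the comparisons rest on, 218 stayed within the counting interval and 134 did not, and of 120 other shares 82 did and 38 did not. Of 200 counts of list members, 186 stayed within 1.5 times the reported count and 14 did not, and of 76 values of r in CD8, CD4, macrophage and neutrophil classes, 69 stayed close and 7 moved. Of 34 values of r in T and NK cells and the B lineage, 29 stayed close and 5 moved. The class II and interferon medians of macrophages and monocytes in Romidepsin/Control and Combination/PD1 turned under none of the alternatives run. Depth limits the Combination library most in gated CD8 cells, of which it held 21. Sums of gated CD8 cells were simulated with counting error only and 200 changed genes per pair. By their interval alone, 2-fold differences were called in 80.6% of cases in Romidepsin/Control (8922 genes) and in 37.3% in Combination/PD1 (8942 genes). The medians and genes that turned, and the shares, counts and values of r the comparisons rest on that moved, are given by setting, while medians, genes and other shares that moved without turning are given as counts only.

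With the stricter cell filter, the T and NK shares were 11.4% in Control, 10.99% in PD1, 8.14% in Romidepsin and 6.92% in Combination. B-lineage shares were 32.3% in Control, 0.469% in PD1, 7.78% in Romidepsin and 1.04% in Combination. Macrophage and monocyte shares were 23.6% in Control, 67.3% in PD1 and 63.0% in Romidepsin. Neutrophil shares were 6.39% in Control, 8.42% in PD1, 5.55% in Romidepsin and 56.1% in Combination. Gated CD8 shares were 20.8% in Control, 45.8% in PD1 and 29.6% in Romidepsin. Gated CD4 shares were 13.1% in Control and 5.37% in PD1. Gzmb was in 37.3% of CD8 cells in Control, 34.6% in PD1, 21.95% in Romidepsin and 63.6% in Combination. Pdcd1 was in 11.8% of CD8 cells in Control, 24.4% in Romidepsin and 9.09% in Combination. Havcr2 was in 15.7% of CD8 cells in Control, 22.6% in Romidepsin and 18.2% in Combination. Tcf7 was in 7.84% of CD8 cells in Control, 3.41% in PD1, 0.61% in Romidepsin and 0% in Combination. Medians in gated CD8 cells turned to -0.075 for the cytotoxic list in Romidepsin/Control, -0.077 for the cytotoxic list in PD1/Control, -0.34 for the exhaustion list in Romidepsin/Control and -0.023 for the exhaustion list in PD1/Control. Medians in gated CD4 cells turned to -0.029 for the exhaustion list in Romidepsin/Control, -0.039 for the exhaustion list in Combination/Romidepsin, 0.084 for the naive list in Romidepsin/Control and 0.21 for the interferon list in PD1/Control. Medians in T and NK cells turned to -0.22 for the cytotoxic list in Combination/Control, -0.024 for the exhaustion list in Romidepsin/Control, -0.20 for the regulatory T cell list in Romidepsin/Control, -0.46 for the T cell chemokine list in Combination/Control and -0.079 for the immediate early list in PD1/Control. PD1/Control in gated CD8 cells had Il6st at 0.048, Pdcd1 at -0.26 and Havcr2 at -0.074. Romidepsin/Control in gated CD8 cells had Havcr2 at -0.22. Combination/Control in gated CD8 cells had Tcf7 at 0.20. Combination/PD1 in gated CD4 cells had Nrgn at -0.78. Romidepsin/Control in gated CD4 cells had Actn1 at 0.33, Trim12a at 0.14 and Ppm1h at 0.21. Combination/Romidepsin in gated CD4 cells had Ccl1 at -2.83 and Tnfsf11 at -1.98. Combination/Control in gated CD4 cells had Foxp3 at -0.11. Higher members of the cytotoxic list were 7 in Romidepsin/Control, 13 in PD1/Control and 2 in Combination/Control. Higher members of the exhaustion list were 2 in Romidepsin/Control, 11 in PD1/Control and 3 in Combination/Control. Lower members of the naive list were 6 in Romidepsin/Control and 9 in Combination/Control. Ccl1 and Tnfsf11 had 0 UMIs in Combination, so their values rest on the 0.5 UMI added, and Gal had 0 in both libraries and has no value. Under this filter a cluster of 243 Control, 211 PD1, 162 Romidepsin and 9 Combination cells, with the mast cell genes Tpsb2, Cma1, Cpa3 and Mcpt4 and then Lef1 and Tcf7 as its leading genes, was left unnamed. Of its cells 238, 210, 156 and 9 were T and NK cells in the reported clustering, so resting T cells left the class and its gates. With the stricter filter and that cluster taken as T and NK cells, the T and NK shares were 26.4% in Control, 14.7% in PD1, 11.8% in Romidepsin and 8.48% in Combination. Gated CD8 share was 36.7% in PD1. Gated CD4 share was 7.31% in Romidepsin. Gzmb was in 31.4% of CD8 cells in PD1, 16.1% in Romidepsin and 66.7% in Combination. Havcr2 was in 19.0% of CD8 cells in Romidepsin and 16.7% in Combination. Tcf7 was in 8.78% of CD8 cells in Romidepsin. Combination/Romidepsin in gated CD8 cells had Sell at 0.005. Pearson r was 0.047 in gated CD4 cells for PD1/Control with Combination/Romidepsin. None of the T cell medians and genes that turned with the stricter filter alone did so with that cluster, and each count of list members stayed within 1.5 times the reported one, so the naming of clusters gave those turns. What moved the shares of the other classes was not traced.

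With no cell filter, the T and NK shares were 10.6% in Control, 11.9% in PD1 and 8.94% in Romidepsin. B-lineage shares were 47.6% in Control and 8.01% in Combination. Macrophage and monocyte shares were 8.85% in Control, 50.8% in PD1, 46.5% in Romidepsin and 26.1% in Combination. Neutrophil shares were 2.26% in Control, 5.47% in PD1, 2.92% in Romidepsin and 37.9% in Combination. Gated CD8 shares were 14.3% in Control and 21.1% in Romidepsin. Gzmb was in 29.5% of CD8 cells in Control and 18.6% in Romidepsin. Havcr2 was in 12.6% of CD8 cells in Control. Tcf7 was in 11.6% of CD8 cells in Control, 4.22% in PD1 and 5.06% in Romidepsin. Pdcd1 was in 23.2% of CD8 cells in Romidepsin. Medians in gated CD8 cells turned to -0.026 for the cytotoxic list in Romidepsin/Control and -0.19 for the exhaustion list in Romidepsin/Control. Median in gated CD4 cells turned to -0.17 for the exhaustion list in Romidepsin/Control. Medians in T and NK cells turned to -0.10 for the cytotoxic list in Combination/Control, 0.18 for the naive list in Combination/PD1, -0.17 for the regulatory T cell list in Romidepsin/Control and -0.037 for the T cell chemokine list in Combination/Control. Combination/Romidepsin in gated CD8 cells had Cmah at 0.62 and Dennd2d at 0.27. Romidepsin/Control in gated CD8 cells had Havcr2 at -0.083. Combination/Control in gated CD8 cells had Tcf7 at 0.21. Combination/Control in gated CD4 cells had Foxp3 at -0.34. Higher members of the cytotoxic list were 3 in Combination/Control. Higher members of the exhaustion list were 3 in Romidepsin/Control and 6 in Combination/Control. With no filter a cluster of 808 Control, 265 PD1, 719 Romidepsin and 18 Combination cells, led by Lef1 and Tcf7, was left unnamed for its few UMIs, so resting T cells left the class here too. With no filter and that cluster taken as T and NK cells, the T and NK shares were 26.8% in Control, 14.7% in PD1, 17.0% in Romidepsin and 14.8% in Combination. Tcf7 was in 8.92% of CD8 cells in PD1. Havcr2 was in 17.9% of CD8 cells in Combination. No T cell median or named gene turned with that cluster, and each count of list members stayed within 1.5 times the reported one. Unnamed clusters that the naming rule placed nearest to macrophages and monocytes held 2112 PD1 cells, and with these the PD1 share of that class was 72.9%. Of the 2112, 464 were in the class in the reported clustering and 1237 were not kept there. They include 721 cells of a cluster led by Ighg2b and mitochondrial genes. A further 169 were in a cluster with keratin genes among its leading genes, so the share may count other cells.

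With CD8 and CD4 cells taken as T cell subclusters, gated CD8 shares were 12.5% in Control, 43.9% in PD1, 61.8% in Romidepsin and 33.8% in Combination. Gated CD4 shares were 16.7% in PD1, 25.3% in Romidepsin and 35.0% in Combination. Medians in gated CD8 cells turned to -0.13 for the cytotoxic list in Romidepsin/Control, -0.51 for the exhaustion list in Romidepsin/Control and 0.31 for the naive list in Romidepsin/Control. Median in gated CD4 cells turned to -0.003 for the exhaustion list in Romidepsin/Control. Romidepsin/Control in gated CD8 cells had Rnf213 at 0.033, Havcr2 at -0.24 and Tcf7 at 0.91. PD1/Control in gated CD8 cells had Dennd2d at 0.10. Combination/PD1 in gated CD8 cells had Gzmb at -0.14. Romidepsin/Control in gated CD4 cells had Igfbp4 at 0.34, Actn1 at 0.74 and Foxp3 at -0.40. Combination/PD1 in gated CD4 cells had Actn1 at 0.12. Combination/Romidepsin in gated CD4 cells had Tnfsf11 at -0.038, Ube2c at 0.38, Hist1h1b at 1.62, Birc5 at 2.67 and Hist1h2ae at 0.88. Combination/Control in gated CD4 cells had Lgals7 at -0.90, Cenpe at 1.91 and Foxp3 at -0.43. Pearson r was -0.105 in gated CD8 cells for Romidepsin/Control with Combination/PD1 and -0.338 in gated CD8 cells for PD1/Control with Combination/Romidepsin. Lgals7 had 0 UMIs in Combination, Gal in Combination and Control, Nrgn in Romidepsin and Control, and Ccl1 in Combination and Romidepsin, so the last 3 have no value here. In this setting a subcluster of 424 Control, 12 PD1, 19 Romidepsin and 3 Combination cells, with Lef1 at 569 CPM, was taken as neither CD8 nor CD4, and one of 5, 13, 351 and 2 cells, with Lef1 at 830 CPM, as CD8. Resting cells were thus left out of Control and kept in Romidepsin, which goes with the changes in CD8 cells of Romidepsin/Control.

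Thinned to 2000 UMIs, gated CD8 shares were 22.4% in Control, 44.9% in PD1 and 35.1% in Romidepsin. Gated CD4 shares were 27.6% in Control, 16.7% in PD1 and 15.3% in Romidepsin. Tcf7 was in 41.4% of CD8 cells in Control, 11.7% in PD1 and 21.2% in Romidepsin. Gzmb was in 41.1% of CD8 cells in PD1 and 23.1% in Romidepsin. Pdcd1 was in 32.6% of CD8 cells in PD1 and 31.9% in Romidepsin. Havcr2 was in 26.9% of CD8 cells in PD1, 20.9% in Romidepsin and 23.8% in Combination. Without thinning, gated CD8 shares were 23.7% in Control, 44.9% in PD1 and 36.0% in Romidepsin. Gated CD4 shares were 42.2% in Control, 22.9% in PD1, 21.2% in Romidepsin and 50% in Combination. Gzmb was in 21.3% of CD8 cells in Control, 48.2% in PD1 and 27.4% in Romidepsin. Pdcd1 was in 18.8% of CD8 cells in Control, 49.3% in PD1, 43.1% in Romidepsin and 61.9% in Combination. Havcr2 was in 18.8% of CD8 cells in Control, 47.1% in PD1, 34.9% in Romidepsin and 38.1% in Combination. Tcf7 was in 58.9% of CD8 cells in Control, 16.1% in PD1 and 29.7% in Romidepsin. Both keep more UMIs per cell by construction, so more cells hold a UMI of a given gene.

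With doublets kept, the T and NK shares were 14.6% in PD1 and 13.2% in Romidepsin. B-lineage share was 9.46% in Romidepsin. Macrophage and monocyte shares were 10.97% in Control and 50.2% in PD1. Gated CD4 share was 7.88% in Romidepsin. Pdcd1 was in 14.1% of CD8 cells in PD1. With genes centred within each library before clustering, B-lineage share was 0% in Combination. Macrophage and monocyte shares were 18.8% in Control, 45.0% in PD1, 51.7% in Romidepsin and 38.8% in Combination. Gated CD4 share was 13.8% in Combination. Median in macrophages and monocytes turned to 0.054 for the tumour-associated macrophage list in Romidepsin/Control. Median in the B lineage turned to 0.17 for the cell cycle list in PD1/Control. Pearson r was 0.405 in macrophages and monocytes for Romidepsin/Control with Combination/PD1 and -0.341 in macrophages and monocytes for PD1/Control with Combination/Romidepsin. With 0 B-lineage cells of Combination left, comparisons of that class with Combination have no value under centring. At resolution 2, macrophage and monocyte shares were 11.7% in Control and 54.9% in PD1. At resolution 0.5, macrophage and monocyte share was 67.6% in PD1. Unnamed clusters nearest to macrophages and monocytes held 1641 PD1 cells with doublets kept, 1259 at resolution 2 and 2047 under centring, and with these the PD1 share was 69.1%, 70.8% and 70.8%, against 70.8% for the reported clusters counted alike. Of those cells 1240, 859 and 1670 were in the class in the reported clustering. Keratin genes were among the leading genes of clusters with 149 PD1 cells at resolution 2, 151 under centring and 153 as reported. Ighg1 led a cluster with 278 PD1 cells under centring, so these may be other cells. The PD1 shares thus follow the naming of clusters for the most part, and the other changes were not traced.

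With the mean over cells, medians in macrophages and monocytes turned to -0.093 for the myeloid chemokine list in Romidepsin/Control and -0.021 for the deacetylase inhibitor response list in Combination/Control. Combination/Romidepsin in gated CD4 cells had Hist1h1b at 0.36. Without genes near the predicted free RNA, Pearson r was 0.30 in gated CD4 cells for Romidepsin/Control with Combination/PD1 and 0.080 in gated CD4 cells for PD1/Control with Combination/Romidepsin. The cause was not tested. With the 2-fold bound, higher members of the exhaustion list were 4 in Romidepsin/Control and 7 in Combination/Control. Lower members of the naive list were 8 in Romidepsin/Control. A wider bound passes fewer members by construction.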

Other observations

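B-lineage cells fell into 3 clusters that split by library. Cluster c0, led by Ighd and Fcer2a, genes of mature B cells that have not switched class, held 95.8% of the B lineage in Control, 89.5% in PD1, 1.003% in Romidepsin and 5.13% in Combination. Cluster c1 held 3.09%, 10.53%, 89.1% and 74.4% of them, with Ighg1 and Jchain, genes of antibody-secreting cells, among its leading genes. At resolution 2 these genes led only a cluster of 63 cells (52 of Romidepsin), while a B-lineage cluster of 627 cells (552 of Romidepsin) was led by Iglc2, Cd79b and Ms4a1. Those genes therefore do not mark c1 as a whole. Cluster c19, led by Mzb1, held 1.15%, 0% (0 of 57 cells, which allows up to 5.26%), 9.89% and 20.5%. Of cell cycle genes, 23 of 33 were higher and 1 lower in Romidepsin/Control (median 1.06, 10000 random lists below), with Birc5 at 2.30 (1.98 to 2.64) and Pclaf at 1.53 (1.35 to 1.72). In Combination/PD1 28 of 31 were higher, at a median of 3.33, or 2.68 with members at 0 at their bound. Oxidative phosphorylation genes had 10 of 21 (0.55) and 19 of 21 members higher (1.29), with Cox5a at 0.99 and 2.10.

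Immediate early genes of the B lineage had 16 of 27 members lower and 3 higher in Romidepsin/Control (-1.03, 0 random lists below), and 19 of 25 lower in Combination/PD1 (-1.32, 0 below). Nr4a3, induced by the antigen receptor, was at -2.80 (-3.11 to -2.52) and -2.63 (-3.54 to -1.82), and Egr3 at -3.08 and -2.13. Class II presentation genes had 8 of 12 members lower (-1.07, 93 below) and 5 of 12 (-0.57, 806 below), with Ciita at -2.70 (-2.88 to -2.53) and -1.33 (-1.81 to -0.84) and H2-Oa at -1.31 and -1.89. The B lineage held 57 PD1 and 39 Combination cells, and the median-of-ratios scaling would add 0.56 to Romidepsin/Control and 0.39 to Combination/PD1 values, so the class II median of -0.57 lies close to that shift.

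Although the titles carry a CD45 tag, epithelial or tumour cells were 7.03% of Romidepsin cells (6.44 to 7.67), 1.01% of PD1 (0.801 to 1.26) and 0.538% of Control (0.319 to 0.849). There were 0 of 716 in Combination. At resolution 0.5 the class also took in some cells of the unnamed cluster c17, which is led by keratin genes too, and held 40 Control, 115 PD1, 580 Romidepsin and 4 Combination cells, so the class is not shown to be absent from Combination. Dendritic cells were 5.74% of Control (4.97 to 6.58), 4.83% of PD1, 4.40% of Romidepsin and 2.65% of Combination cells (1.61 to 4.11). Plasmacytoid dendritic cells were 0.926%, 0.353%, 0.614% and 0.14% in that order.

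Exhaustion genes in gated CD4 cells had 16 of 24 members higher and 0 lower in PD1/Control (0.998, 10000 random lists below), and 6 of 21 in Combination/Romidepsin (0.42, 10000 below). Pdcd1 in these cells was at 2.04 (1.66 to 2.45) and 0.84 (0.43 to 1.23). The Combination/Romidepsin median was -0.04 with the stricter cell filter, and 0.33 with the T cell cluster that this filter left unnamed.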
